A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

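Per the labels, poly(A) RNA of Saccharomyces cerevisiae S288c was labelled with Cy3 (the YPD, SCD or untreated sample) and Cy5 (the MDN or rapamycin-treated sample) and compared on 6 arrays of 2 channels, with no dye swap. The table holds the values as the authors deposited them, 6210 probes by 6 arrays, on a log2 scale: raised to the power of 2, 100% of them are whole multiples of 0.01 (tolerance 0.0001), so they are base-2 logs of ratios kept to 2 decimals, and the lowest ratio possible is 0.01, or -6.64. This scale was found from the values. Direction was read as Cy5 over Cy3 from the dyes in the labels and the usual form of such ratios, and is likely rather than stated. Scanner, background correction, normalization, spot filtering, treatment time and rapamycin dose are not given in the sources used here. Array medians were -0.06 for MDN over YPD, -0.09 for MDN over SCD, 0.04 and 0.07 for rapamycin in MDN and 0.01 and 0.00 for rapamycin in YPD, so the deposited ratios were close to centred, by a method that stays unknown. Missing probes numbered 121, 275, 317, 376, 89 and 181 in the same order. They were not mostly low ratios: of probes missing on 1 rapamycin array, between 1.82% and 2.80% were below -2 on its partner, against 3.87% to 5.08% of all probes. Rounding matters for low ratios, since a ratio near 0.02 is known to within a step of 0.01; between 74 and 86 probes per MDN rapamycin array had a ratio of 0.05 or less, and 36 and 19 on the YPD ones.

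Probes were named from the platform annotation given with the series. A single symbol was given for 5595 probes, none had several, and 615 were unnamed here. All 5595 matched the RefSeq gene table of the current yeast assembly by gene number and symbol. The 34 genes with several probes were averaged, giving 5560 genes. No coordinates are printed, because the build of the array design is not given. Probes for near-identical copies, such as the paired ribosomal protein genes, ASP3, CUP1 and IMD genes, may share signal.

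The rapamycin arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean per medium, so that both media share an estimate of the spread. Tests were two-sided against 0 for each medium and for the difference MDN minus YPD. Genes and unnamed probes with a value on all 4 arrays were tested, 5488 in total (4996 named), and those with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The fit had 2 residual degrees of freedom and 3.00 from the variance prior, and a typical standard error was 0.096 for a medium mean and 0.136 for the difference; the number of arrays limits the precision. The 2 medium arrays have no replicate and no test: genes with an absolute log2 ratio of at least 1 were counted, and a list median was placed among those of 10000 random lists of the same size, not matched on expression because no level is held here. SCD over YPD was the difference of these arrays. Gene lists, 39 in all, were tested with camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. The latter asks whether the genes of a list move on balance one way, without comparing them with other genes. Lists, tests, thresholds, the naming rule and all but 2 of the alternatives were chosen before the data were examined. Genes were named by rule: the 10 highest and 10 lowest called genes of each comparison with arrays agreeing in sign (the 10 largest in each direction for medium arrays), up to 4 members of each list with the largest absolute value, called ones first, and a fixed set of TOR, nitrogen, stress and amino acid genes, of which FPR1 had no value usable here, NSR1 and RPL25 lacked a value on some arrays, and another gene is not reported here.

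The test was checked on simulated data in which 50 genes were changed by each of 4 known folds. In MDN it recovered 40%, 94%, 98% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, in YPD 54%, 98%, 96% and 100%, and for the difference 8%, 70%, 90% and 100%. Of 500 random lists of 20 genes, 0.8% had a camera p under 0.05. Genes were simulated independently of each other, so this check does not cover lists whose genes are correlated. Alternatives were median centring, equal scale of arrays, genes with at least 1 array per medium, probes tested separately, a replicate block, a robust prior, rules of fold size, other set tests, and each array left out in turn, in which the lone array of a medium is assumed to vary like the other medium; ratios floored at 0.05 and a crossed block were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.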

Results

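The series measured relative transcript levels in Saccharomyces cerevisiae S288c, the reference laboratory strain of budding yeast, on 6 arrays that each compared a pair of dye-labelled poly(A) RNA samples. Rapamycin is a macrolide that binds the prolyl isomerase Fpr1 and inhibits the TOR kinase, which couples growth to nutrient supply. A group of 2 arrays set rapamycin-treated against untreated cells in MDN, and another 2 did the same in YPD, a standard rich medium. Of the remaining arrays, 1 set MDN against YPD and 1 set MDN against SCD. The labels give MDN and SCD as abbreviations only. The design asks which genes respond to TOR inhibition in MDN, with the other media for comparison. Between 5834 and 6121 of the 6210 probes had a value on each array, and array medians lay between -0.09 and 0.07 on the log2 scale. Arrays of the same kind correlated across probes with r = 0.966 in MDN and r = 0.950 in YPD, and the median replicate SD of a gene was 0.13. Positive values are read as higher with rapamycin, or higher in MDN, because the treated or MDN sample carried Cy5 in the labels. This direction is likely but not stated with the values, and every direction given here would turn over together if the ratio was formed the other way. All 6 arrays had the same dye orientation, so a dye effect of a single probe stays in each value and cancels only in differences between arrays. The labels do not say that arrays came from separate cultures, so p-values of single genes measure only the spread between these arrays, which may be technical. Camera's p-values instead compare the genes of a list with the other genes at the preset correlation. A very small one rests on the number of genes and on that setting, not on replicate arrays. Errors written after ± are standard errors from the limma fit with n = 2 arrays per medium, and list tests are limma's camera. An estimated-correlation p is camera's adjusted p when the correlation between the genes of a list is estimated from the arrays instead of preset.

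With rapamycin in MDN, transcripts of the translation machinery were far lower and those of several nitrogen, stress and protein turnover genes were higher. The cytosolic ribosomal proteins fell in 127 of 128 measured members (127 changed adjusted over the list alone, list median -4.32, adjusted p = 1.24e-46, estimated-correlation p = 0.355). The strongest increases were those of BAT2, the cytosolic branched-chain amino acid transaminase, at 3.93 ± 0.17 (15.2-fold, n = 2), and TMT1, the trans-aconitate methyltransferase, at 3.87 ± 0.15. DAL5, an allantoate permease, rose by 3.58 ± 0.17. DIP5, a permease for dicarboxylic amino acids, rose by 3.28 ± 0.12, and MLS1, malate synthase, by 3.25 ± 0.23. ALT1, an alanine transaminase, rose by 2.93 ± 0.10 and HSP26, a small heat shock protein, by 2.89 ± 0.11. YHI9 at 3.60, BSC5 at 2.92 and YOR338W at 2.88 completed the 10 highest. At the other end, RPS0A, RPS16B, RPL17A and RPL6A each stood at -6.14, with 1 of the 2 arrays at the smallest ratio the deposited values can take. RPL2A, RPL8B, RPL9A and RPS0B, all ribosomal proteins, were at -5.64, the same value as ASC1, a protein of the small ribosomal subunit. The lowest of all was the probe annotated as YBT1, an ATP-binding cassette transporter of the vacuole, at -6.64 on both arrays. That is the ratio 0.01, the smallest possible, so the sizes and ranks of these 5 genes are uncertain. The YBT1 probe read like those of ribosomal proteins, and whether its annotation names the right gene was not settled here. By limma with Benjamini-Hochberg adjustment, 2968 of 5488 genes and unnamed probes changed, 1690 up and 1278 down. Of these, 758 changed at least 2-fold, 470 of them down. Among these 20 genes adjusted p lay between 1.41e-05, reached by RPL9A and 4 others, and 0.000488 for MLS1, each gene with the same sign on both arrays. With only 1 MDN array the count of calls dropped to 540 (201 up and 339 down, without MDN array 1) or 656 (281 up and 375 down, without MDN array 2), so that most calls were then down. Up and down were close under median centring (1498 and 1460) and at equal array scale (1672 and 1618). All 2968 genes kept their sign with any 1 array left out, which a call in the full fit already ensures. These 20 genes passed under median centring and at equal array scale. That was nearly certain for genes this far from 0, so it adds little support.

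Gene groups for protein synthesis, fixed before the data were examined like every list used here, passed the camera test with a downward direction in MDN. The ribosomal proteins had the lowest camera adjusted p, 1.24e-46, and an estimated-correlation p of 0.355. Ribosome biogenesis genes fell in 93 of 107 members and rose in 2 (97 changed adjusted over the list alone, median -1.29, adjusted p = 2.89e-23, estimated-correlation p = 0.306). Within that list, the box C/D snoRNP proteins NOP58 and NOP56 stood at -3.95 ± 0.10 and -3.84 ± 0.12. EMG1, an rRNA methyltransferase, was at -3.32 ± 0.08. Translation factors fell in 33 of 36 members (33 adjusted over the list alone, median -1.18, adjusted p = 2.42e-13, estimated-correlation p = 0.355), with elongation factor YEF3 at -2.22 ± 0.08. Aminoacyl-tRNA synthetases fell in 18 of 21 and rose in 1 (20 adjusted over the list alone, adjusted p = 6.14e-07, estimated-correlation p = 0.355), led by YHR020W, the prolyl-tRNA synthetase, at -1.76 ± 0.08. RNA polymerase I and III genes fell in 15 of 32 and rose in 5 (20 adjusted over the list alone, adjusted p = 0.00638, estimated-correlation p = 0.355). RPA43 and RPA12, subunits of polymerase I, were at -3.25 ± 0.09 and -2.03 ± 0.09. Without MDN array 1 or MDN array 2, the members that fell numbered 105 or 107 ribosomal proteins, 39 or 42 biogenesis genes, 16 or 18 translation factors, 7 or 7 synthetases and 4 or 6 polymerase genes. The polymerase genes that rose numbered 1 or 0, and 3 without either YPD array. The biogenesis genes that rose numbered 0 or 0, and 1 without either YPD array, and no synthetase rose with any 1 of the 4 arrays left out.

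Purine biosynthesis was the metabolic list with the lowest median in MDN, at -1.45. Of its 20 measured members 17 fell and none rose (17 adjusted over the list alone, adjusted p = 2.64e-08, estimated-correlation p = 0.306). ADE17, which carries out the closing steps of inosine monophosphate synthesis, stood at -3.47 ± 0.08. The inosine monophosphate dehydrogenase genes IMD4, IMD3 and IMD2 were at -4.35 ± 0.16, -3.66 ± 0.11 and -3.40 ± 0.17. The IMD genes are close in sequence, so their probes may share signal. Lysine biosynthesis fell in 6 of 7 members (6 adjusted over the list alone, adjusted p = 0.00069, estimated-correlation p = 0.355), with LYS12 and LYS9 both at -2.44 ± 0.09 and LYS4 at -2.19 ± 0.09. In branched-chain amino acid biosynthesis 6 of 11 fell and 2 rose (10 adjusted over the list alone, adjusted p = 0.0247, estimated-correlation p = 0.355, and adjusted p = 0.0510 at equal array scale). BAT1, LEU2 and ILV5 stood at -2.79 ± 0.09, -2.74 ± 0.11 and -2.47 ± 0.14 and BAT2 at 3.93. Sulfur assimilation and methionine genes fell in 14 of 26 and rose in 3 (19 adjusted over the list alone, adjusted p = 0.00611, estimated-correlation p = 0.355). Glycolysis genes fell in 13 of 21 and rose in 4 (18 adjusted over the list alone, adjusted p = 0.00609, estimated-correlation p = 0.355). Phosphate regulon genes fell in 10 of 14 and rose in 1 (11 adjusted over the list alone, adjusted p = 0.00376, estimated-correlation p = 0.437). MUP1, the methionine permease, was at -2.26 ± 0.11. ADH1, the main fermentative alcohol dehydrogenase, was at -1.58 ± 0.11, and PHO84, the high-affinity phosphate transporter, at -1.94 ± 0.08. SHM2, the cytosolic serine hydroxymethyltransferase, fell by 3.84 ± 0.08, although its list of threonine, serine and glycine genes did not pass (adjusted p = 0.0524). Without MDN array 1 or MDN array 2, members that fell numbered 10 or 11 for purines, 3 or 3 for lysine, and 5 or 5 for branched-chain amino acids. In the same order they numbered 5 or 5 for sulfur, 3 or 6 for glycolysis and 3 or 4 for the phosphate regulon, for which the number was 6 without either YPD array. Those that rose numbered 1 or 1 for sulfur, 1 or 1 for glycolysis and 1 or 2 for branched-chain amino acids without MDN array 1 or MDN array 2.

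Upward changes in MDN covered stress, turnover and respiratory lists. General stress genes rose in 32 of 41 members and fell in 1 (35 changed adjusted over the list alone, median 0.81, adjusted p = 6.14e-07, estimated-correlation p = 0.382), with the aldehyde dehydrogenases ALD3 and ALD2 at 2.17 ± 0.14 and 1.96 ± 0.08. Proteasome subunit genes rose in 29 of 31 (29 adjusted over the list alone, median 0.73, adjusted p = 1.57e-07, estimated-correlation p = 0.306), for example PRE3 at 1.11 ± 0.08 and RPT1 at 1.03 ± 0.08. Autophagy genes rose in 17 of 21 (17 adjusted over the list alone, adjusted p = 0.000206, estimated-correlation p = 0.355), among them ATG31 at 1.37 ± 0.08. Vacuolar protease genes rose in 5 of 7 (5 adjusted over the list alone, adjusted p = 0.00376, estimated-correlation p = 0.355), among them the proteinase B gene PRB1 at 1.60 ± 0.12. That list also holds PBI2, a proteinase B inhibitor, and YPS1, a cell surface protease. Nitrogen catabolite repression genes, which are held down on preferred nitrogen sources, rose in 19 of 29 and fell in 4 (23 adjusted over the list alone, adjusted p = 0.00367, estimated-correlation p = 0.453). The near-identical ASP3 copies, whose probes may share signal, count as 4 separate members in the counts and tests of this list. GAP1, the general amino acid permease, was at -0.91 ± 0.10, whereas OPT2, an oligopeptide transporter, was at 2.52 ± 0.13. The list of retrograde pathway genes, called retrograde targets here, rose in 8 of 11 (10 adjusted over the list alone, adjusted p = 0.00331, estimated-correlation p = 0.355), with CIT2, the peroxisomal citrate synthase, at 2.13 ± 0.11. It also holds the pathway regulators RTG1, RTG2, RTG3 and MKS1, and shares CIT1, ACO1, IDH1 and IDH2 with the tricarboxylic acid cycle list. Tricarboxylic acid cycle genes rose in 12 of 14 (13 adjusted over the list alone, adjusted p = 0.00111, estimated-correlation p = 0.421). Arginine biosynthesis rose in 5 of 8 (5 adjusted over the list alone, adjusted p = 0.0119, estimated-correlation p = 0.496) and histones in 7 of 10 (7 adjusted over the list alone, adjusted p = 0.0128, estimated-correlation p = 0.496). The respiratory chain rose in 15 of 31 with 2 lower (17 adjusted over the list alone, adjusted p = 0.0323, estimated-correlation p = 0.355) and ergosterol genes in 11 of 23 (10 adjusted over the list alone, adjusted p = 0.0247, estimated-correlation p = 0.666). Without MDN array 1 or MDN array 2 the members that rose numbered 8 or 15 for stress, 4 or 5 for the proteasome, 5 or 7 for autophagy and 5 or 8 for nitrogen. In the same order they numbered 2 or 2 for retrograde targets, 0 or 1 for the tricarboxylic acid cycle, 3 or 3 for arginine, 1 or 1 for ergosterol, and 0 or 0 for histones and the respiratory chain, whose list call was also lost without MDN array 1 (adjusted p = 0.0520). GAP1 lost its call without MDN array 2 (adjusted p = 0.0557). Histidine genes (3 of 7 rose, 3 fell, 6 adjusted over the list alone, adjusted p = 0.839) and heat shock chaperones (11 of 17 rose, 2 fell, 13 adjusted over the list alone, adjusted p = 0.0771) did not pass as lists. In the fits without MDN array 1 or MDN array 2, 1 or 2 chaperone genes rose and 1 or 1 fell, no histidine gene passed, the nitrogen genes that fell numbered 2 or 0, and no stress or respiratory chain gene fell.

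**Figure D1:**
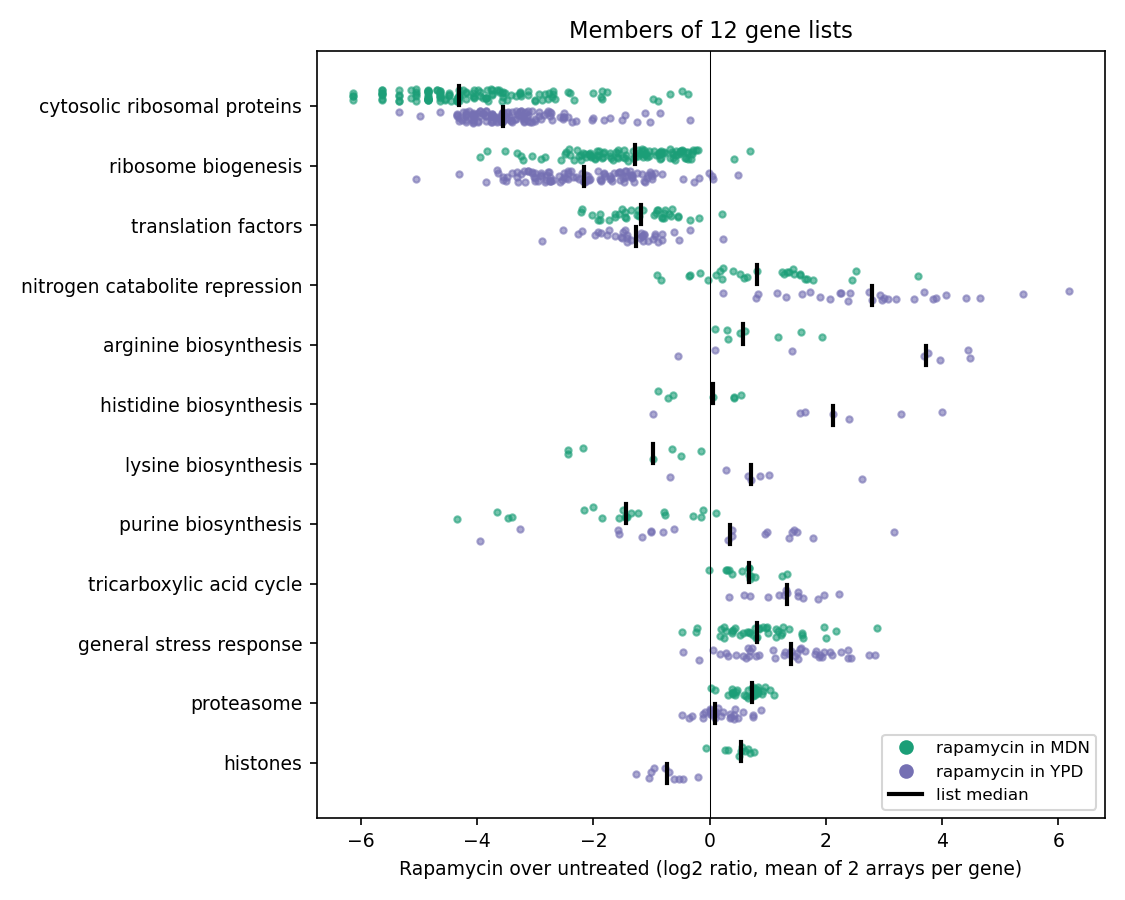
Mean log2 ratio of rapamycin-treated over untreated cells on the horizontal axis for the members of 12 gene lists, with green points for MDN and violet points for YPD (each point a gene, mean of 2 arrays) and black bars for list medians. Ribosomal proteins lie far below 0 in both media, while arginine, histidine and nitrogen catabolite repression genes lie higher in YPD (medians 3.72, 2.12 and 2.80) than in MDN (0.57, 0.06 and 0.82).

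With rapamycin in YPD, nitrogen catabolite repression genes rose in 28 of 29 measured members (29 changed adjusted over the list alone, adjusted p = 2.3e-11, estimated-correlation p = 0.309). Ribosomal proteins fell in 126 of 128 (128 adjusted over the list alone, adjusted p = 7.81e-32, estimated-correlation p = 0.309). GAP1 rose by 6.18 ± 0.10 (72.6-fold, n = 2). MEP2, an ammonium permease, rose by 5.38 ± 0.15 (41.8-fold) and DAL5 by 4.65 ± 0.17. TMT1 rose by 5.62 ± 0.15 and SNZ1, a gene of vitamin B6 synthesis, by 5.11 ± 0.19. The arginine synthesis genes ARG1 and ARG4 rose by 4.48 ± 0.08 and 4.45 ± 0.12. ARO5 at 4.92, YPL088W at 4.45 and CPS1, a vacuolar carboxypeptidase, at 4.41 ± 0.10 were also among the 10 highest. The 10 lowest were ribosomal or assembly genes in most cases. RPS22A was at -5.35 ± 0.47, RPS3 at -4.98 ± 0.32, RPL9A at -4.64 ± 0.08, RPL42B, RPL5 and RPL6A each at -4.35, and RPS10A at -4.32. UTP13, a small subunit processome protein, was at -5.06 ± 0.80 with the smallest possible ratio on YPD array 2, BRX1, a ribosome assembly factor, at -4.32 ± 0.09, and LIA1, deoxyhypusine hydroxylase, at -4.35 ± 0.15. limma with Benjamini-Hochberg adjustment called 3638 of 5488 genes and unnamed probes, 1884 up and 1754 down, with 597 and 632 of them at least 2-fold. Among these 20 genes adjusted p ranged from 2.41e-05 for GAP1 to 0.00384 for UTP13, with the same sign on both arrays. The count of calls was 2388 without YPD array 1 and 2527 without YPD array 2. RPS22A lost its call without YPD array 1 or YPD array 2, and UTP13 without YPD array 2. All 3638 genes kept their sign, which a call in the full fit already ensures.

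Nitrogen catabolite repression genes in YPD had a median of 2.80, and 26 of the 28 that rose did so at least 2-fold (adjusted p = 2.3e-11, estimated-correlation p = 0.309). DAL80, a repressor of nitrogen genes, stood at 3.85 ± 0.09 and GLN1, glutamine synthetase, at 2.26 ± 0.08. Arginine biosynthesis rose in 6 of 8 members and fell in 1 (7 adjusted over the list alone, median 3.72, adjusted p = 0.00405, estimated-correlation p = 0.442). Histidine biosynthesis rose in 6 of 7 and fell in 1 (7 adjusted over the list alone, adjusted p = 0.00627, estimated-correlation p = 0.309), with HIS5 at 3.99 ± 0.09 and HIS4 at 3.30 ± 0.18. Aromatic amino acid genes rose in 9 of 14 and fell in 2 (11 adjusted over the list alone, adjusted p = 0.0115, estimated-correlation p = 0.309). ARO9, an aromatic aminotransferase, was at 4.01 ± 0.12. Branched-chain genes rose in 7 of 11 and fell in 1 (8 adjusted over the list alone, adjusted p = 0.0182, estimated-correlation p = 0.309), including LEU4 at 2.71 ± 0.08. Threonine, serine and glycine genes rose in 9 of 15 and fell in 3 (12 adjusted over the list alone, adjusted p = 0.0385, estimated-correlation p = 0.33), including GCV2, a glycine decarboxylase subunit, at 3.16 ± 0.09 and SHM2 at 2.33 ± 0.08. The list did not pass without YPD array 1 (adjusted p = 0.0749), MDN array 1 or MDN array 2 (0.0574 for each). Retrograde targets rose in 10 of 11 and fell in 1 (11 adjusted over the list alone, adjusted p = 0.00151, estimated-correlation p = 0.309), with the lactate dehydrogenase gene DLD3 at 3.27 ± 0.11 and CIT2 at 3.16 ± 0.11. Tricarboxylic acid cycle genes rose in 13 of 14 (13 adjusted over the list alone, adjusted p = 2.18e-05, estimated-correlation p = 0.342). Lysine biosynthesis, in which 6 of 7 rose and 1 fell (7 adjusted over the list alone), did not pass as a list (adjusted p = 0.0614). Nor did purine biosynthesis, in which 11 of 20 rose and 9 fell (20 adjusted over the list alone, adjusted p = 0.761). ADE17 stood at 3.18 ± 0.08 and GUA1, GMP synthase, at -3.27 ± 0.13. Sulfur and methionine genes rose in 8 of 26 and fell in 9 (17 adjusted over the list alone, adjusted p = 0.918), and amino acid and peptide permeases rose in 6 of 15 and fell in 6 (12 adjusted over the list alone, adjusted p = 0.844). With any 1 of the 4 arrays left out the lysine genes that rose numbered 4, and without YPD array 2 the threonine, serine and glycine genes that fell numbered 1. No retrograde target fell without either YPD array, no arginine gene without YPD array 1 or either MDN array, and 1 aromatic gene without either MDN array.

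Ribosomal proteins in YPD fell in 126 of 128 members (128 adjusted over the list alone, median -3.56, adjusted p = 7.81e-32, estimated-correlation p = 0.309). Ribosome biogenesis genes fell in 100 of 107 with 1 higher (102 adjusted over the list alone, median -2.16, adjusted p = 9.32e-23, estimated-correlation p = 0.309). Translation factors fell in 34 of 36 (34 adjusted over the list alone, adjusted p = 4.64e-11, estimated-correlation p = 0.309) and RNA polymerase I and III genes in 20 of 32 with 5 higher (25 adjusted over the list alone, adjusted p = 0.000348, estimated-correlation p = 0.309). Aminoacyl-tRNA synthetases fell in 11 of 21 with 3 higher (14 adjusted over the list alone, adjusted p = 0.0385, estimated-correlation p = 0.559, and adjusted p = 0.0962 without YPD array 1). Histones fell in 9 of 10 members (9 adjusted over the list alone, median -0.73, adjusted p = 0.00151, estimated-correlation p = 0.435), with the histone H4 genes HHF1 and HHF2 at -1.26 ± 0.12 and -1.04 ± 0.08. G1 and S phase genes fell in 10 of 18 with 1 higher (11 adjusted over the list alone, adjusted p = 0.0118, estimated-correlation p = 0.309), with the polymerase clamp gene POL30 at -1.60 ± 0.09 and the cyclin CLB5 at -1.17 ± 0.09. General stress genes rose in 35 of 41 (38 adjusted over the list alone, median 1.39, adjusted p = 9.11e-09, estimated-correlation p = 0.33), including the trehalase gene NTH1 at 2.38 ± 0.09. Autophagy genes rose in 18 of 21 with 1 lower (19 adjusted over the list alone, adjusted p = 0.000348, estimated-correlation p = 0.309), including ATG8 at 2.13 ± 0.13, and vacuolar protease genes rose in 7 of 7 (7 adjusted over the list alone, adjusted p = 0.00108, estimated-correlation p = 0.309). The respiratory chain rose in 22 of 31 with 1 lower (23 adjusted over the list alone, adjusted p = 0.00108, estimated-correlation p = 0.309). The phosphate regulon fell in 10 of 14 with 1 higher (11 adjusted over the list alone, adjusted p = 0.0118, estimated-correlation p = 0.442). Ergosterol genes rose in 12 of 23 (12 adjusted over the list alone, adjusted p = 0.0323, estimated-correlation p = 0.578). Those that rose numbered 9 and 5 without YPD array 1 and YPD array 2 and 7 without either MDN array, and there was no list call without YPD array 2 (adjusted p = 0.119). Proteasome genes rose in 11 of 31 and fell in 3 (13 adjusted over the list alone, adjusted p = 0.135). Without YPD array 1 or YPD array 2 the respiratory chain genes that rose numbered 13 or 15, the autophagy genes 12 or 13, and the phosphate regulon genes that fell 8 or 6. Without MDN array 1 or 2 the G1 and S phase genes that fell numbered 6. Polymerase genes that rose numbered 1 or 2 without YPD array 1 or YPD array 2 and 3 without either MDN array. No G1 and S phase gene rose with any 1 of the 4 arrays left out, no respiratory chain gene fell without either YPD array, and 2 autophagy genes fell without YPD array 2. Synthetases that rose numbered 1 without either YPD array, and proteasome genes that fell numbered 1 with any 1 of the 4 arrays left out.

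The rapamycin responses in the media were compared by a direct test of their difference, which removes constant dye effects. GAP1 had the lowest difference, MDN minus YPD, at -7.09 ± 0.15, with means of -0.91 in MDN and 6.18 in YPD. ADE17 differed by -6.65 ± 0.12 (-3.47 in MDN, 3.18 in YPD) and SHM2 by -6.16 ± 0.11 (-3.84 and 2.33). MEP2 differed by -5.17 ± 0.21 (0.22 and 5.38) and GCV2 by -5.05 ± 0.12 (-1.89 and 3.16). ARO9 and ARO10, which act in breakdown of aromatic amino acids, differed by -5.12 ± 0.17 and -4.86 ± 0.13. SNZ1 differed by -4.28 ± 0.26, HIS4 by -3.93 ± 0.26 and the allantoin degradation gene DAL3 by -3.85 ± 0.15. In the opposite direction, the amino acid permease TAT1 differed by 2.84 ± 0.22 (0.21 in MDN, -2.63 in YPD) and the oligopeptide transporter OPT1 by 2.73 ± 0.19. The arginine methyltransferase RMT2 differed by 2.55 ± 0.19, the flavohemoglobin YHB1 by 2.50 ± 0.14 and the pyruvate decarboxylase isozyme PDC6 by 2.16 ± 0.22. The copper metallothioneins CUP1-1 and CUP1-2, near-identical copies whose probes cannot be read apart, differed by 2.12 ± 0.16 and 2.02 ± 0.14. The hexose transporters HXT2 and HXT5 differed by 2.09 ± 0.14 and 2.03 ± 0.21. MXR1, a methionine sulfoxide reductase, had the highest difference, 3.97 ± 0.98, but its YPD arrays read -1.25 and -4.32. In the limma test with Benjamini-Hochberg adjustment 1620 of 5488 genes and unnamed probes differed, 819 higher and 801 lower in MDN (750 and 930 under median centring, 605 and 865 at equal array scale), and 169 and 327 of them by at least 2-fold. Adjusted p among these 20 genes ran from 9.29e-05 to 0.0377. No difference passed once any 1 of the 4 arrays was left out: the limma count was 0 in each case, and 1495, 1495, 2030 and 2159 genes had an unadjusted p under 0.05 without MDN array 1, MDN array 2, YPD array 1 and YPD array 2. All 1620 kept their sign in those fits. A call in the full fit already ensures this, so it adds no support.

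**Figure D2:**
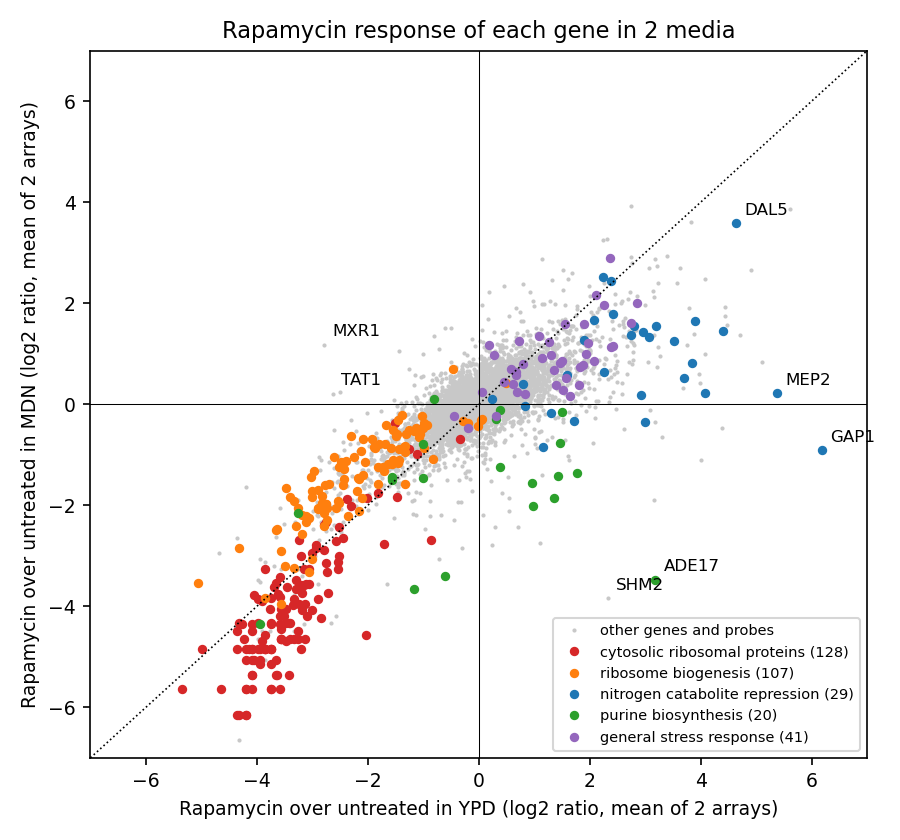
Mean log2 ratio of rapamycin-treated over untreated cells in YPD (horizontal) and in MDN (vertical), 2 arrays each, with grey points for genes and unnamed probes and coloured points for 5 lists, the dotted line marking equal values. GAP1, MEP2, ADE17 and SHM2 lie far to the right of the line, with differences of -7.09, -5.17, -6.65 and -6.16, and the ribosomal proteins lie at low values in both media.

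Several amino acid synthesis lists had lower rapamycin responses in MDN than in YPD in the test of the difference. Here lower refers to the response to rapamycin, not to the transcript level. Nitrogen catabolite repression genes, for example, had a median of 1.92 for MDN over YPD on the single medium array. Histidine genes were lower in 6 of 7 members (6 adjusted over the list alone, median difference -2.06, adjusted p = 2.22e-05, estimated-correlation p = 0.26) and arginine genes in 6 of 8 (8 adjusted over the list alone, median -2.54, adjusted p = 0.00145, estimated-correlation p = 0.409). Lysine genes were lower in 6 of 7 (7 adjusted over the list alone, median -1.84, adjusted p = 2.97e-06, estimated-correlation p = 0.26), and branched-chain genes in 9 of 11 with 1 higher (10 adjusted over the list alone, median -1.51, adjusted p = 5.21e-06, estimated-correlation p = 0.26). LEU2, of leucine synthesis, differed by -3.84 ± 0.15 and HIS5 by -3.57 ± 0.12. CPA1, of carbamoyl phosphate synthesis, differed by -3.36 ± 0.12 and LYS9 by -3.14 ± 0.13. Aromatic amino acid genes were lower in 8 of 14 and higher in 2 (12 adjusted over the list alone, adjusted p = 0.000203, estimated-correlation p = 0.26). Threonine, serine and glycine genes were lower in 8 of 15 and higher in 1 (10 adjusted over the list alone, adjusted p = 0.00132, estimated-correlation p = 0.26). The purine list was lower in 12 of 20 and higher in 2 (15 adjusted over the list alone, median -1.63, adjusted p = 7.42e-06, estimated-correlation p = 0.26). Nitrogen catabolite repression genes were lower in 22 of 29 (24 adjusted over the list alone, median -1.61, adjusted p = 2.03e-11, estimated-correlation p = 0.26). DAL5, at -1.06 ± 0.25 (adjusted p = 0.0321), turned to 0.064 (adjusted p = 0.811) when arrays were brought to equal scale. The tricarboxylic acid cycle was lower in 10 of 14 (12 adjusted over the list alone, median -0.72, adjusted p = 2.22e-05, estimated-correlation p = 0.372). No single member passed the limma test with any 1 of the 4 arrays left out.

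Among growth genes the rapamycin responses in the media differed in both directions. Ribosome biogenesis genes were higher in MDN, that is less reduced by rapamycin, in 53 of 107 members with 54 not passing (59 adjusted over the list alone, median difference 0.73, adjusted p = 2.68e-11, estimated-correlation p = 0.26). Ribosomal proteins instead were lower in 54 of 128 and higher in 1 (65 adjusted over the list alone, median -0.67, adjusted p = 3.99e-10, estimated-correlation p = 0.409). Many ribosomal protein ratios in MDN lie between 0.01 and 0.05, where a step of 0.01 is coarse. RPS0A and RPL17A lost their call with ratios floored at 0.05, an alternative chosen after seeing the data. Histones were higher in MDN in 10 of 10 members (10 adjusted over the list alone, median 1.17, adjusted p = 2.09e-06, estimated-correlation p = 0.322), HHF1 by 1.95 ± 0.17 with means of 0.69 and -1.26. G1 and S phase genes were higher in 7 of 18 (11 adjusted over the list alone, adjusted p = 8.24e-05, estimated-correlation p = 0.26), CLB5 by 1.55 ± 0.12. Proteasome genes were higher in 17 of 31 (20 adjusted over the list alone, median 0.48, adjusted p = 1.75e-06, estimated-correlation p = 0.26). Without any 1 of the 4 arrays no member of these lists passed the limma test. Over the 39 lists camera called 22 in MDN (11 up, 11 down), 22 in YPD (14 up, 8 down) and 24 for the difference (6 up, 18 down). With an estimated correlation, which leaves 2 residual degrees of freedom, camera called 0 in each, the lowest adjusted p being 0.306, 0.309 and 0.26, with 4, 3 and 6 lists at an unadjusted p under 0.05. The alternative test fry called 30, 31 and 25.

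Across genes, the responses in MDN and YPD correlated with r = 0.80 and rho = 0.722 over 5488 genes, which are not independent replicates. Of the genes called in each medium, 1226 rose in both and 981 fell in both, where lists drawn independently would share 580.2 and 408.5. Part of such an overlap may come from the common dye orientation. A set of 90 rose in MDN and fell in YPD, and 81 fell in MDN and rose in YPD, with 540.1 and 438.7 for independent lists. Each of them was also called in the test of the difference, which follows from opposite calls in a shared fit and adds no support. All 90 and 81 lost that call with any 1 array left out. CTT1, cytosolic catalase, rose in MDN (1.58 ± 0.11, adjusted p = 0.0511 without MDN array 1) and in YPD (1.55 ± 0.11). The difference was 0.03 ± 0.16 (adjusted p = 0.883). Of the TOR kinase genes, TOR1 was at -0.18 ± 0.12 (adjusted p = 0.265) in MDN and -0.47 ± 0.12 (adjusted p = 0.0212, 0.131 without YPD array 1 and 0.0862 without either MDN array) in YPD. TOR2 was at -0.25 ± 0.14 (adjusted p = 0.186) and 0.16 ± 0.14 (adjusted p = 0.358). GCN4, the activator of amino acid synthesis genes, rose by 0.80 ± 0.09 in YPD and by 0.28 ± 0.09 in MDN (adjusted p = 0.0473, lost under median centring, equal array scale, either replicate block and with genes of at least 1 array per medium). Without MDN array 1, MDN array 2 or either YPD array the adjusted p of GCN4 in MDN was 0.298, 0.157 and 0.0658. RPL25, a ribosomal protein gene left out of the test, was at 0.15 on MDN array 1 and -0.06 on YPD array 1. It had no value on the other rapamycin arrays. NSR1, without a value on MDN array 1, was at -2.18 on MDN array 2 and at -4.32 and -3.47 on the YPD arrays.

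Growth in MDN against YPD, seen on 1 array without a replicate, went with far higher levels of nitrogen, sulfur and arginine genes. GAP1 was at 6.75 (107-fold), MEP2 at 6.30 (79-fold), DAL80 at 5.04 and DAL5 at 4.20. The asparaginase genes ASP3-3, ASP3-2 and ASP3-1, near-identical copies, read 4.46, 4.38 and 4.33. ARG3, ornithine carbamoyltransferase, was at 4.86, MET3, ATP sulfurylase, at 4.22 and MET6, methionine synthase, at 4.11. Lower in MDN were the amino acid permeases BAP3 at -5.06, BAP2 and TAT1 at -4.06 and TAT2 at -3.06, and the serine and threonine deaminase CHA1 at -4.64. Others were the peptide transporter PTR2 at -3.64, the ferric reductase FRE1 at -3.47, BAT2 and the hexose transporter HXT2 at -3.06 and the thiamine-regulated phosphatase PHO3 at -2.94. At least 2-fold differences numbered 238 higher and 119 lower among 6056 genes and unnamed probes. Nitrogen catabolite repression genes had a median of 1.92, above 100% of 10000 random lists of the same size. The same held for sulfur assimilation at 1.60, arginine at 2.16, lysine at 1.26, vacuolar proteases at 1.30, general stress genes at 0.78 and glycolysis at 0.70. HSP12, a membrane-associated stress protein, was at 4.02. Amino acid and peptide permeases had a median of -1.13, ribosome biogenesis genes of -0.58 and ribosomal proteins of -0.38, each below all random lists. With arrays brought to equal scale the counts were 450 and 253. That setting widens the ratios of this array, so the cut then lies below 2-fold of the deposited ratios.

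Against SCD, also on 1 array, MDN again went with higher nitrogen genes, while sulfur genes had a smaller median of 0.17 (percentile 99.96 of the random lists, 17 of 26 higher). GAP1 was 64.0-fold higher, MEP2 was at 5.89, DAL80 at 5.22, DAL5 at 3.99 and PUT1, proline oxidase, at 3.42. The ASP3 copies ASP3-2, ASP3-3, ASP3-1 and ASP3-4 read 5.44, 5.04, 4.69 and 4.67, and LEE1 was at 3.66. ZRT1, the high-affinity zinc transporter, was lowest at -6.64, the smallest ratio possible, followed by BAP3 at -5.64, CHA1 at -5.06, BAP2 at -4.32 and ZPS1, a zinc-regulated cell surface protein, at -4.06. TAT1 at -3.06, INO1, of inositol synthesis, at -2.94, MUP1 at -2.84, YGP1, a secreted stress glycoprotein, at -2.64, and GNP1, a glutamine permease, at -2.47 were next. At least 2-fold differences numbered 141 higher and 58 lower of 5901. Against both media, 105 genes and unnamed probes were at least 2-fold higher in MDN and 25 lower, where independent lists would share 5.73 and 1.18. Those values leave out that the arrays have the same dye orientation and may share MDN RNA. Over 5812 genes the medium arrays correlated at r = 0.578 (rho = 0.317), against a simulated r of 0.501 for shared MDN RNA with no effect, and the covariance was 0.176 against 0.0229. List medians above all random lists included those of nitrogen catabolite repression (2.11), lysine (1.86), arginine (1.35), branched-chain amino acids (1.25) and purines (0.75). The zinc regulon, at -0.84, and permeases, at -1.69, lay below all of them. With arrays brought to equal scale the counts were 477 and 179, again with a cut below 2-fold of the deposited ratios.

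**Figure D3:**
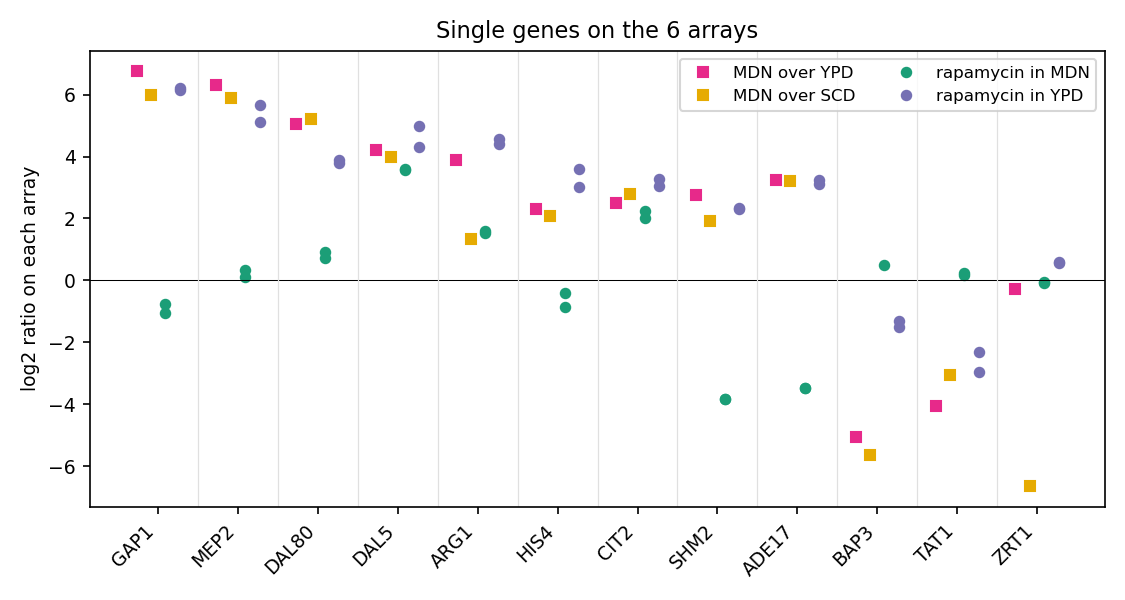
Log2 ratios of 12 genes on each of the 6 arrays, with squares for the MDN over YPD and MDN over SCD arrays and circles for the rapamycin arrays in MDN (green) and YPD (violet). GAP1, MEP2 and DAL80 are high on both medium arrays and with rapamycin in YPD, while ADE17 and SHM2 are low with rapamycin in MDN (-3.47 and -3.84).

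The difference of those arrays gives SCD over YPD, in which a dye effect cancels. ZRT1 was 6.38 higher in SCD, but its value on the SCD array was the smallest possible, so the size and rank of this difference are uncertain. ZPS1 was higher by 4.36, MET3 by 4.04, HSP12 by 3.91 and MET14 by 3.81. MET6 was higher by 3.74, INO1 by 3.73, MET17 by 3.40, OPI3, a phospholipid methyltransferase, by 3.23 and the sulfate permease SUL2 by 3.14. BAT2 was lower in SCD at -3.45, as were the acid phosphatases PHO11 and PHO12 at -3.36 and -2.85, and the reductase FRE7 at -2.69. Also lower were the phosphate genes PHM6 and SPL2 at -2.09 and -1.82, HXT2 at -1.70, arginase CAR1 at -1.61, PHO89 at -1.60 and PHO3 at -1.58. Among others, sulfur genes had a median of 1.25 and general stress genes of 0.88, above all random lists. The phosphate regulon had a median of -0.97, below all of them, while nitrogen catabolite repression genes were at -0.12 (percentile 7.25). In total 160 genes and unnamed probes were at least 2-fold higher in SCD and 124 lower, of 5812. With arrays brought to equal scale, where the cut is no longer 2-fold, the numbers were 354 and 483.

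Medium and rapamycin responses had their highest correlation for YPD. Over 5422 genes, MDN over YPD correlated with the rapamycin response in YPD at r = 0.483 (rho = 0.488) and with that in MDN at r = 0.242 (rho = 0.342). MDN over SCD correlated with the response in YPD at r = 0.255 (rho = 0.168) and with that in MDN at r = 0.0477 (rho = 0.0413), over 5404 genes. Whether arrays shared untreated RNA is not stated. Had they done so with no effect at all, simulated correlations would be 0.506, -0.476, 0 and -0.508 in that order. The covariances were 0.335, 0.148, 0.143 and 0.0236, against simulated values of 0.0233, -0.0215, 0 and -0.0231. The simulations took their spread from arrays of the same kind, which may be technical and leave out deviations of a shared culture. GAP1, MEP2, DAL80 and ARG1, the last at 3.87 on the MDN over YPD array, were high in MDN and with rapamycin in YPD.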

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

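The test of a dye effect on the ribosomal proteins was chosen only after the result was seen. The test of the difference between MDN and YPD passed for 1620 genes and unnamed probes, including 90 that rose in MDN and fell in YPD and 81 that did the opposite; all 1620 lost their call with any 1 of the 4 arrays left out, when limma called 0 and 1495, 1495, 2030 and 2159 had an unadjusted p under 0.05 (without MDN array 1, MDN array 2, YPD array 1 and YPD array 2). Differences, MDN minus YPD, were highest for MXR1 (3.97), TAT1 (2.84), OPT1 (2.73), RMT2 (2.55), YHB1 (2.50), PDC6 (2.16), CUP1-1 (2.12), HXT2 (2.09), HXT5 (2.03) and CUP1-2 (2.02). MXR1 lost its call when genes with at least 1 array per medium were tested (adjusted p = 0.050). The lowest were those of GAP1 (-7.09), ADE17 (-6.65), SHM2 (-6.16), MEP2 (-5.17), ARO9 (-5.12), GCV2 (-5.05), ARO10 (-4.86), SNZ1 (-4.28), HIS4 (-3.93) and DAL3 (-3.85).

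Camera called 24 of 39 lists for the difference of the rapamycin responses, so higher and lower in MDN refer to the response and not to the level. With an estimated correlation it called 0, the lowest adjusted p being 0.26 with 6 at an unadjusted p under 0.05, and fry called 25. Of the 24 lists, those higher in MDN had medians of 1.17 (histones), 0.73 (ribosome biogenesis), 0.51 (G1 and S phase), 0.48 (proteasome), 0.36 (heat shock chaperones) and 0.34 (RNA polymerase I and III). Biosynthetic and nitrogen lists lower in MDN had medians of -2.54 (arginine), -2.06 (histidine), -1.84 (lysine), -1.63 (purines), -1.61 (nitrogen catabolite repression), -1.51 (branched-chain amino acids), -1.02 (aromatic amino acids), -0.91 (threonine, serine and glycine), -0.54 (glutamate, proline and asparagine) and -0.53 (sulfur and methionine). The others lower in MDN were the tricarboxylic acid cycle (-0.72), ribosomal proteins (-0.67), vacuolar proteases (-0.59), glycolysis (-0.54), retrograde targets (-0.44), aminoacyl-tRNA synthetases (-0.33), general stress (-0.32) and the respiratory chain (-0.26). Left-out arrays ended the camera call of sulfur genes (adjusted p = 0.0534, 0.0525 and 0.117 without MDN array 1, YPD array 1 and YPD array 2), chaperones (0.0532 and 0.144 without MDN array 1 and YPD array 1), vacuolar proteases (0.0672 and 0.0696 without YPD array 1 and YPD array 2) and glutamate genes (0.153 without YPD array 2). At equal array scale the calls of polymerase I and III (0.275), retrograde (0.119), glutamate (0.105), respiratory (0.105), stress (0.333) and vacuolar protease genes (0.266) were lost as well. With a replicate block 1 list lost its call for the difference and 1 gained it.

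The low values of the ribosomal protein genes, with a median of -4.32 in MDN (camera adjusted p = 1.24e-46, and adjusted p = 0.355 with an estimated correlation), were weighed against 3 technical explanations. Rounding can hide at most 0.005 of a ratio, and with every ratio raised by 0.005 the median was -4.18. That is an arithmetic bound on the effect of rounding, fixed by the median itself, and not an independent test. A dye effect of the probes would also act on the medium arrays, of the same orientation and without rapamycin, where the lower of the list medians was -0.38. The 16 members without an A or B copy had a median of -4.48, so the fall was not limited to paired copies. RPL25, also without such a copy, was not among them because of missing values. It did not fall where measured (0.15 on MDN array 1 and -0.06 on YPD array 1). Shared signal mixes the ratios of copies, and this comparison cannot test it among the paired ones. A fall of these transcripts with rapamycin stays as a biological hypothesis, found and tested on the same arrays.

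Purine biosynthesis genes were lower with rapamycin in MDN and not, as a list, in YPD, with a median difference of -1.63 (camera adjusted p = 2.64e-08, 0.761 and 7.42e-06 in MDN, in YPD and for the difference). With an estimated correlation the adjusted p was 0.306 in MDN and 0.26 for the difference, so both calls were lost. No member passed limma's test of the difference with any 1 of the 4 arrays left out, and those that fell in MDN numbered 10 or 11 instead of 17 without MDN array 1 or MDN array 2. Under median centring or equal scale of the arrays the higher of the list medians was -1.52. The medians of the rapamycin arrays lay between 0.00 and 0.07, so centring could hardly have moved it and was no real test. A single deviating array did not account for it, as the highest median with any 1 of the 4 arrays left out was -1.62. A response that depends on the medium is a biological hypothesis that may explain it; whether it comes from purines supplied by a medium was not tested.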

How the results depend on the processing

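Ratios floored at 0.05 and the crossed pairing were chosen only after the data were seen. Over all alternatives, 5302 values of named genes kept their side of the threshold, 8 of them with another sign while called in neither setting, 850 were weaker, 15 stronger and 1 reversed. For lists the numbers were 1278 (17 of them with another sign), 94, 32 and 0. DAL5 reversed in the difference at equal array scale (0.064, limma adjusted p = 0.811). Its responses were 3.58 in MDN and 4.65 in YPD. Equal scale narrows the YPD arrays, whose median absolute deviations were 0.714 and 0.689 against 0.547 and 0.503 in MDN. The reversal follows from that rescaling. With any 1 array left out, genes higher in MDN numbered 201 to 1460 and lower 339 to 1147, those higher in YPD 1260 to 1518 and lower 1128 to 1373, and limma called 0 higher and 0 lower for the difference, with 1495 to 2159 at an unadjusted p under 0.05; fewer arrays leave fewer degrees of freedom. With an estimated correlation camera called 0 lists in MDN, 0 in YPD and 0 for the difference (4, 3 and 6 at an unadjusted p under 0.05, fry called 30, 31 and 25). This changes both the correlation and the degrees of freedom, and the cause was not tested. A rule of adjusted p with at least 2-fold change gave 758 of 2968 in MDN, 1229 of 3638 in YPD and 496 of 1620 for the difference, stricter by construction. A rule of at least 2-fold on both arrays without a test gave 236 higher and 431 lower, 515 and 567, and 92 and 225. It adds a fold size and drops the test, and the cause was not tested. On the medium arrays, whose spread was smaller, equal scale widened the ratios, so the cut was no longer 2-fold. It gave 450 higher and 253 lower for MDN over YPD, and 477 and 179 for MDN over SCD. For SCD over YPD the numbers were 354 and 483. The cause of these changes was not tested further. A log2 ratio of at least 1.5, stricter by construction, gave 125 and 30, 63 and 27, and 60 and 16. The correlation of MDN over YPD with the rapamycin response in MDN was 0.342 as Spearman's rho; the cause of its rise from r = 0.242 was not tested. Median centring moved the split in MDN from 1690 and 1278 to 1498 and 1460, and that of the difference from 819 and 801 to 750 and 930, or 605 and 865 at equal array scale.

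Arrays of the same number share only that number, and their deviations correlated at -0.10 across genes. A replicate block gave 1544 higher and 1165 lower in MDN, 1784 and 1633 in YPD and 562 and 623 for the difference. The crossed pairing called 1606 and 1224, 1815 and 1717, and 683 and 704. Signal over background is not held here, so its limit on low ratios was not analysed.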

Other observations

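The covariance test for shared untreated RNA was chosen only after the result was seen. Several genes outside the groups described so far changed with rapamycin in both media. HMX1, heme oxygenase, rose by 2.87 ± 0.14 in MDN and 3.17 ± 0.14 in YPD, although the iron regulon did not pass in either (6 of 20 rose and 4 fell in MDN, 11 adjusted over the list alone, adjusted p = 0.839; 9 rose and 3 fell in YPD, 12 adjusted over the list alone, adjusted p = 0.248). Without MDN array 1 or MDN array 2 1 iron gene rose in MDN and none fell, against 3 higher without either YPD array, and with any 1 of the 4 arrays left out 5 rose in YPD. ADR1, an activator of genes for growth on non-fermentable carbon, was at -3.77 ± 0.16 and -3.33 ± 0.16, while MDH2, cytosolic malate dehydrogenase, was at 2.23 ± 0.12 in MDN. SSB2, a ribosome-associated chaperone, was at -3.25 ± 0.12 and -3.27 ± 0.12. Its near-identical copy SSB1 was at -0.86 ± 0.08 in MDN (adjusted p = 0.0591 and 0.0556 without MDN array 1 and MDN array 2) and, with the other sign, at 1.06 ± 0.08 in YPD, and the probes of these copies may share signal. In pyrimidine synthesis, URA1 was at -2.38 ± 0.14 and -2.60 ± 0.14 and its pathway member URA10 at 2.13 ± 0.16 in MDN (adjusted p = 0.0531 and 0.0528 without MDN array 1 and MDN array 2) and 2.85 ± 0.16 in YPD. PRM1, a membrane protein of mating, was at 1.29 ± 0.10 and 1.62 ± 0.10.

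In YPD, the list of thiamine, pyridoxine and biotin genes rose in 16 of 24 members and fell in 1 (18 adjusted over the list alone; median 0.57; camera adjusted p = 0.00925, and adjusted p = 0.309 with an estimated correlation). SNO1, of vitamin B6 synthesis, was at 4.08 ± 0.23 and BIO3, of biotin synthesis, at 1.75 ± 0.09. Without YPD array 1 or YPD array 2 the members that rose numbered 10. In MDN 11 of 24 rose and 3 fell (15 adjusted over the list alone; adjusted p = 0.470), with 1 or 2 higher and 0 or 1 lower without MDN array 1 or MDN array 2, and the test of the difference gave an adjusted p of 0.0661.

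Chaining the arrays (MDN over YPD, plus the rapamycin response in MDN, minus that in YPD) gives the ratio of the media with rapamycin. For 236 genes at least 2-fold higher in MDN than in YPD the median was 1.52 without and 0.807 with rapamycin. Of these, 190 were smaller in absolute size and 58 changed sign, among them SHM2 (2.74 to -3.42) and ADE17 (3.23 to -3.43), which ended farther from 0, and HIS4 (2.29 to -1.64). For 109 genes at least 2-fold lower the medians were -1.22 and -0.788. Genes at least 2-fold lower in MDN than in SCD had medians of -0.556 and -0.592, and over all genes the SD was 0.620 without and 0.686 with rapamycin. Without the nitrogen list the fall of the median was 0.684, so that list alone was not the whole of it. Chance values of untreated RNA shared between arrays would give a covariance of at most the error variance of an array. The covariance was 4.10 times that variance, which would speak against them. That variance may be technical and is then no upper limit, so a response to rapamycin cannot be told apart here from such values. Selection of genes on the noise of the YPD array would leave genes chosen on the SCD array nearly unchanged, whereas they fell by 1.45. The medium arrays may share MDN RNA, so selection on noise cannot be told apart either.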
